A study of Homo sapiens with 6 samples.

How the data were processed

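Gene expression was measured on 6 Affymetrix GeneChip arrays, 3 from the human breast cancer line MDA-MB-468GFP (the parental line below) and 3 from MDA-MB-468GFP-LN (the LN line below). Per the labels, the first is the parental line and served as the control group, and the second was the experimental group. Each array held RNA of a separate biological replicate, grown in α-MEM with fetal calf serum, extracted with an RNeasy kit and labelled by the one-cycle protocol, per the labels' protocols.

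The deposited values are probe set intensities on a linear scale, computed with MAS5 per the labels and the submitters' processing notes. In MAS5, the signals of the probes of a probe set are combined and each array is scaled by 1 factor. In the deposited values the trimmed mean of every array was 150 signal units, and no further normalization was applied. The number of arrays limits the precision, and the files used here hold no detection calls, so a low signal was not separated from background. The authors' deposited comparison table gives a signed fold change per probe set, treated here as a score because decreases carry a minus sign. Per its header, that table holds probe sets detected on at least 1 of the 6 arrays and changed at least 2-fold after an analysis of variance with Benjamini-Hochberg adjustment in Genespring. Its decreases stop at a limit of 100-fold, which 113 probe sets reached in the authors' deposited table, so the lower 5 of that table have no order. Further deposited tables list probe sets of genes taken from published studies of lymphatic metastasis and of stem cell-like properties, with the study each came from.

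No annotation of the array's probe sets was used here beyond these deposited tables, so a probe set is named only where they pair it with a gene. Of 7243 probe sets in them, 6309 had 1 symbol, 6 had several and 928 had none. In the RefSeq gene table of assembly GRCh38.p14, 4161 of the 6309 symbols were current, 1170 were replaced through a single synonym and 978 were kept as given. Names of 5668 probe sets came from the authors' comparison table, which was selected on these same arrays, and 641 from the literature tables alone. Counts of changed members in a gene list therefore describe mostly probe sets that the authors had found changed by at least 2-fold. List members without a named probe set were not tested. Such a count is not independent evidence that a list changed; its split into higher and lower members was not part of that selection.

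The table held 54675 probe sets, of which 62 were controls. Probe sets were tested where the mean signal over all 6 arrays was at or above the median of such means, a signal of 42.5, which left 27307. The test used log2 of the signal plus a pseudocount of 16 in limma 3.58.1 under R 4.3.3, with an intensity trend in the variance and no covariate. A probe set was called changed at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Fold changes on this scale understate the change of low signals, so mean signals per line are given for most named genes. Ratios against a mean signal near background are imprecise. All adjusted p-values in the text come from limma unless another test is named.

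The gene lists were written before the data were examined: 30 gene lists and 7 lists of markers of cell types that the cultures should not hold. Each gene was represented by the probe set with the highest mean signal among its tested probe sets that the deposited tables name. A brighter probe set of the same gene without a name there could not be chosen. For some genes the one used may therefore be dim and selected for its change. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the 28 testable lists, and again with an estimated correlation. Camera compared each list with the other tested named genes, not with all tested probe sets. Of these 4088 named genes, 3962 were called changed. The rotation test fry was run beside it. The published lists were compared with all tested probe sets by Fisher's exact test, two-sided, and with 10000 random lists matched on mean signal in 20 bins, one-sided; these tests were added after the data were seen.

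Genes named in the text follow a rule written before the data were examined. It takes the 12 largest changes each way among called genes whose arrays did not overlap between lines and whose higher mean signal reached the 75th percentile. It adds up to 2 members each way of every list, 13 genes of prior interest and the 5 largest changes each way in the authors' deposited table. Some genes that the rule takes are not reported here. Further list members, RB1, SMAD4 and the melanocyte markers were chosen after their values or those of related genes were seen. Some probe sets, such as those of TMSB4X, CTAG1B and CTAG2, can also read near-identical relatives, so their signals are not assigned with certainty to 1 gene.

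The procedure was tested on simulated arrays of the 27307 probe sets. With the LN line set against the parental line, 80% of changes of 1 and 100% of changes of 2 on the log2 scale were recovered, and 5.26% of the calls were unchanged probe sets. With no change simulated, 0 probe sets were called. Over 4088 genes, 5 of 5 shifted lists were recovered and 0 of 15 unshifted lists were called. The simulation drew independent noise for each probe set and changed only a small share of them, and in the list test nothing outside the shifted lists. In the real arrays 58.5% of tested probe sets changed, and genes can be correlated. The simulated error rates therefore do not carry over to the calls made here, least of all to those of lists.

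Alternatives covered pseudocounts of 1 and 64, quantile normalization, median scaling, no filter and a stricter filter, a variance model without the trend, the methods' test per probe set, the replicate number as a block, the mean of all probe sets of a gene, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.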

Results

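The series compared the MDA-MB-468GFP-LN line with the line described as its parent, to find expression differences in a model of breast cancer metastasis. Descent of the LN line was not tested here, and signals that bear on it are given under the other observations. In the following, rose and fell mean higher and lower in the LN line, not a change shown to have occurred in descendants of the parental cells. MDA-MB-468 is an established line from a triple-negative breast carcinoma with basal features, here carrying green fluorescent protein, and the LN line is described as its lymph node metastatic variant. Signals of 54675 probe sets were measured on 3 arrays per line. Median signals per array lay between 36.6 and 40.8. Across probe sets, arrays of the LN line correlated with each other at 0.983 to 0.988 and those of the parental line at 0.956 to 0.985. Correlations between arrays of different lines were 0.668 to 0.701. The first principal component held 90.7% of the variance and separated the lines. In parental replicate 1 the ratio of 3' to 5' signal of the actin control, a measure of RNA integrity, was 2.65, against 1.31 to 1.52 on the other arrays.

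The comparison of the lines asked which genes differed between the LN line and the parental line. Epithelial junction genes were lower in the LN line, with signals between 0.220% and 42.9% of those in the parental line over 30 tested genes. The mean signal of KRT19, a simple-epithelium keratin, was 5467 ± 147 (SD, n = 3) in the parental line and 0.858 ± 0.0939 (SD, n = 3) in the LN line. EGFR, the epidermal growth factor receptor, fell from 5577 ± 827 to 14.1 ± 8.04 (SD, n = 3 each). Conversely, genes of pigment cells were abundant in the LN line: MLANA, a melanosomal protein, rose from 20.1 ± 10.97 to 5109 ± 353 and TYRP1, an enzyme of melanin synthesis, from 13.96 ± 1.43 to 4399 ± 364 (SD, n = 3 each).

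In total, 15981 of 27307 tested probe sets changed, 58.5% of them, with 8149 higher and 7832 lower in the LN line. All replicates of a group came from the same line. The p-values therefore measure spread between replicates, and do not extend to other metastatic variants. At least 2-fold changes on the log2 scale were seen for 7356 probe sets, 3541 higher and 3815 lower. By the ratio of mean signals, 577 called probe sets were at least 10-fold higher and 1023 at least 10-fold lower. The arrays of the lines did not overlap for 17787 tested probe sets, or 65.1%, where chance gives 10%. The median log2 change of all tested probe sets was 0.02. Named probe sets covered 4088 tested genes, of which 1775 rose and 2187 fell.

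Among the largest increases on the log2 scale, CTAG2 rose by 7.36 ± 0.10 (SE, adjusted p = 5.48e-09) and CTAG1B by 7.23 ± 0.10 (SE, adjusted p = 5.48e-09). Both are cancer-testis antigens, normally expressed in germ cells. By the ratio of mean signals, CTAG2 was 1128-fold and CTAG1B 1482-fold higher. MLANA and TYRP1 each rose by 7.20. SPARC, a matricellular glycoprotein, rose by 6.88, BCHE, butyrylcholinesterase, by 6.85, IFI16, a DNA sensor, by 6.64 and S100B, a calcium-binding protein of glia and melanocytes, by 6.57. BEX3 rose by 6.53, FABP7, a fatty acid-binding protein of neural cells, by 6.49 and NOV, a matricellular protein, by 6.48. Mean signals of these genes in the LN line ranged from 1877 for S100B to 5109 for MLANA, and in the parental line from 1.79 for CTAG1B to 39.5 for FABP7.

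Among the largest decreases, the log2 change of KRT19 was -8.35 ± 0.09 (SE, adjusted p = 4.89e-09), that of KRT7 -7.99 ± 0.09 (SE, adjusted p = 5.08e-09) and that of KRT14, a basal keratin, -7.15. By the ratio of mean signals, KRT19 was 6376-fold and KRT7 2435-fold lower. For EGFR the log2 change was -7.57 ± 0.21 (SE, adjusted p = 4.29e-08). The thymosin probe set of TMSB4X changed by -7.59, ALDH1A3, a retinaldehyde dehydrogenase, by -7.41, DKFZP564K0822 by -7.37 and RARRES1, a retinoid-responsive gene, by -7.32. Changes were -7.25 for SLC44A2, a choline transporter-like protein, -7.24 for EPCAM, the epithelial adhesion molecule, and -7.15 for SCGB2A2, or mammaglobin.

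**Figure D1:**
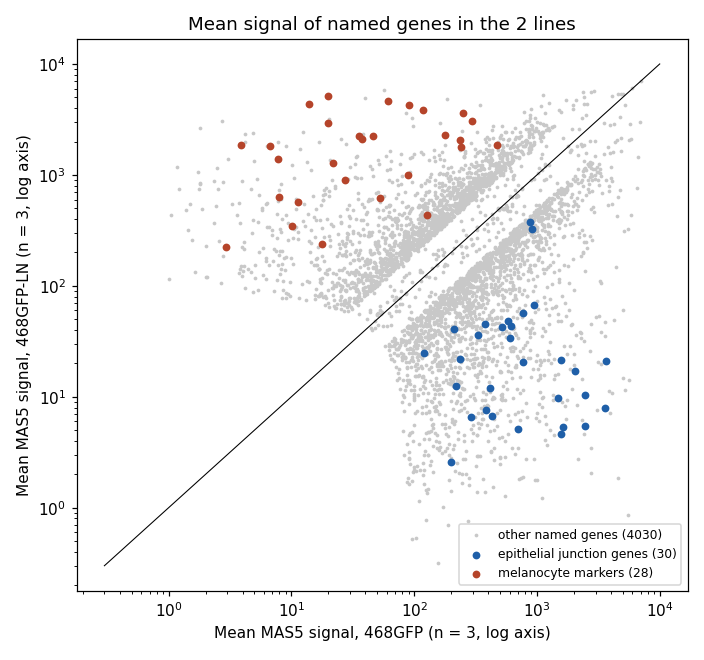
Mean MAS5 signal of each tested named gene in the parental line (horizontal, log axis) and the LN line (vertical, log axis), 3 arrays per line, with the line of equal signal. All 30 tested epithelial junction genes (blue) lie below that line and all 28 tested melanocyte markers (red) above it; the empty band along it reflects naming mostly from a table of changes of at least 2-fold.

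The genes of prior interest moved apart. CDH1, or E-cadherin, fell from 1571 ± 51.7 to 4.63 ± 4.32 while VIM, the intermediate filament vimentin, rose from 56.5 ± 8.05 to 5798 ± 584 (SD, n = 3 each), a log2 change of 6.33. CD24, a surface glycoprotein, fell from 5013 to 60.2, and its 6 tested probe sets all fell. CD44, a hyaluronan receptor, fell from 4777 to 3348 at its brightest named probe set, a log2 change of -0.51 (adjusted p = 0.00024). Of its 11 tested probe sets, 8 fell and 0 rose, with log2 changes from -0.42 to -2.15 among those that fell. SPP1, or osteopontin, rose from 14.5 to 165 and the integrin subunit ITGA9 from 2.76 to 185. CCND1, or cyclin D1, fell from 1012 to 170. MKI67, a proliferation marker, rose from 300 to 607, by 0.97 on the log2 scale. VEGFC, VEGFD and NEDD9 had no named probe set in the tables used here.

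**Figure D2:**
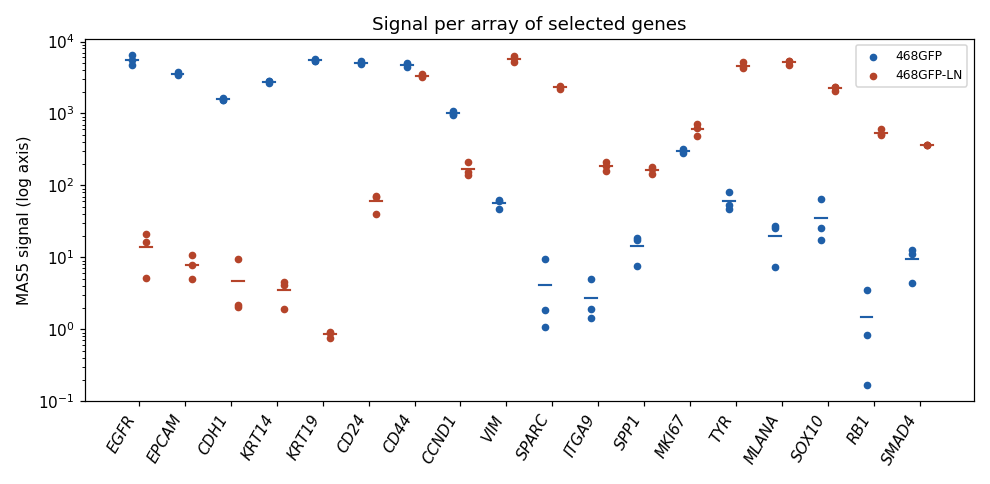
MAS5 signal (log axis) of selected genes on each of the 3 arrays of the parental line (blue) and the LN line (red); short bars are the means. EGFR, for example, had means of 5577 and 14.1, and for every gene shown the arrays of the lines did not overlap.

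Of 36 epithelial junction and identity genes, 30 were tested. Of these, 30 fell and 0 rose, and 30 fell when adjusted over the list alone, with a median log2 change of -3.71 (camera adjusted p = 4.75e-06). That call was lost at adjusted p = 0.258 with an estimated correlation. EPCAM fell from 3576 to 7.86, F11R, a tight junction molecule, from 2449 to 5.44, and DSP, or desmoplakin, from 3626 to 21.1. Basal keratins and basal breast genes fell in 20 of 22 cases and rose in 1, the same counts adjusted over the list alone, with a median of -4.02 (camera adjusted p = 0.000775; adjusted p = 0.258 with an estimated correlation). KRT5 fell from 3294 to 19.9 and KLK5, a kallikrein protease, from 3604 to 47.3. The member that rose was CRYAB, a small heat-shock protein, from 315 to 1466, and ID4 had signals of 631 and 630. Luminal breast genes fell in 15 of 19 cases and rose in 3, and as often adjusted over the list alone, but the list was not called (camera adjusted p = 0.0600). GATA3, a luminal transcription factor, fell from 1443 to 65.8. Beside these epithelial groups, all 28 tested melanocyte markers, a list made after the data were first seen, were higher in the LN line.

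Mesenchymal genes did not move one way: 8 of 22 rose, 9 fell and 5 did not pass, with the same counts of changes adjusted over the list alone (camera adjusted p = 0.696). SNAI2, a transcriptional repressor, rose from 8.97 to 1826, ZEB2 from 1.22 to 753 and CDH2, or N-cadherin, from 3.30 to 550. However, S100A4 fell from 1901 to 44.4, COL1A1 from 357 to 6.36 and ZEB1 from 334 to 97.6. Integrins rose in 4 and fell in 6 of 11 cases (5 and 6 adjusted over the list alone; camera adjusted p = 0.894). ITGA4 rose from 7.60 to 446, while ITGB6, an epithelial integrin, fell from 808 to 2.77. Extracellular matrix genes rose in 9 and fell in 12 of 22 cases, also adjusted over the list alone (camera adjusted p = 0.894). This list holds NOV under its newer symbol CCN3, so NOV, which rose by 6.48 on the log2 scale, was not counted. TNC, or tenascin C, rose from 114 to 1609 and FBLN1 fell from 727 to 6.13. Proteases and their inhibitors rose in 8 and fell in 11 of 23 cases, also adjusted over the list alone (camera adjusted p = 0.894). SERPINE2 rose from 185 to 4799 and TIMP2 from 507 to 2300, while KLK6 fell from 2434 to 32.0.

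Members of EGF receptor signalling split: 10 of 23 rose and 12 fell, also adjusted over the list alone (camera adjusted p = 0.958; the median, -1.06, and the camera direction, up, differ in sign). EGFR fell together with its ligands TGFA, from 620 to 16.7, and AREG, from 434 to 9.49. The feedback phosphatase DUSP6 rose from 259 to 1222, the ETS factor ETV5 from 132.9 to 1359 and SPRY4, an inhibitor of receptor tyrosine kinase signalling, from 279 to 1051. HBEGF, a further ligand, rose from 50.4 to 483. Stem cell and progenitor markers rose in 6 and fell in 7 of 14 cases, also adjusted over the list alone (camera adjusted p = 0.985; median -0.24, camera direction up). NES, or nestin, rose from 73.7 to 668 and PROM1 fell from 564 to 39.0. Lymphangiogenic and angiogenic factors rose in 3 and fell in 5 of 8 cases, also adjusted over the list alone (camera adjusted p = 0.894). NRP2, a co-receptor for VEGF-C, rose from 6.36 to 556 and EFNB2 fell from 883 to 26.2.

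Of 51 oxidative phosphorylation genes on the list, only 7 had a named probe set. These rose in 7 of 7 cases, and in 7 adjusted over the list alone. Most of the list was not tested. Only 1 of the 7 was named from outside the authors' table of changes of at least 2-fold. Members that changed less would mostly have stayed unnamed, so these counts do not show that the list as a whole rose. The median log2 change was 1.35 (camera adjusted p = 0.0272, and adjusted p = 0.351 with an estimated correlation). CYC1, a subunit of complex III, rose from 883 to 3239 and SDHB, of complex II, from 320 to 1202. Hypoxia and glycolysis genes rose in 14 of 20 cases and fell in 4, also adjusted over the list alone, and were not called (camera adjusted p = 0.0600). NDRG1 rose from 72.6 to 893, whereas the glucose transporter SLC2A1 fell from 559 to 247 and LDHA had signals of 4868 and 5312. Cholesterol and fatty acid synthesis genes fell in 12 and rose in 5 of 17 cases, also adjusted over the list alone (camera adjusted p = 0.455). HMGCS1 fell from 1073 to 209 and SCD, a desaturase, rose from 295 to 871. Genes of MHC class I presentation fell in 6 and rose in 2 of 8 cases, also adjusted over the list alone (camera adjusted p = 0.530), with HLA-B falling from 1013 to 229. Mitotic and S-phase genes rose in 6 and fell in 4 of 11 cases, also adjusted over the list alone (camera adjusted p = 0.696).

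**Figure D3:**
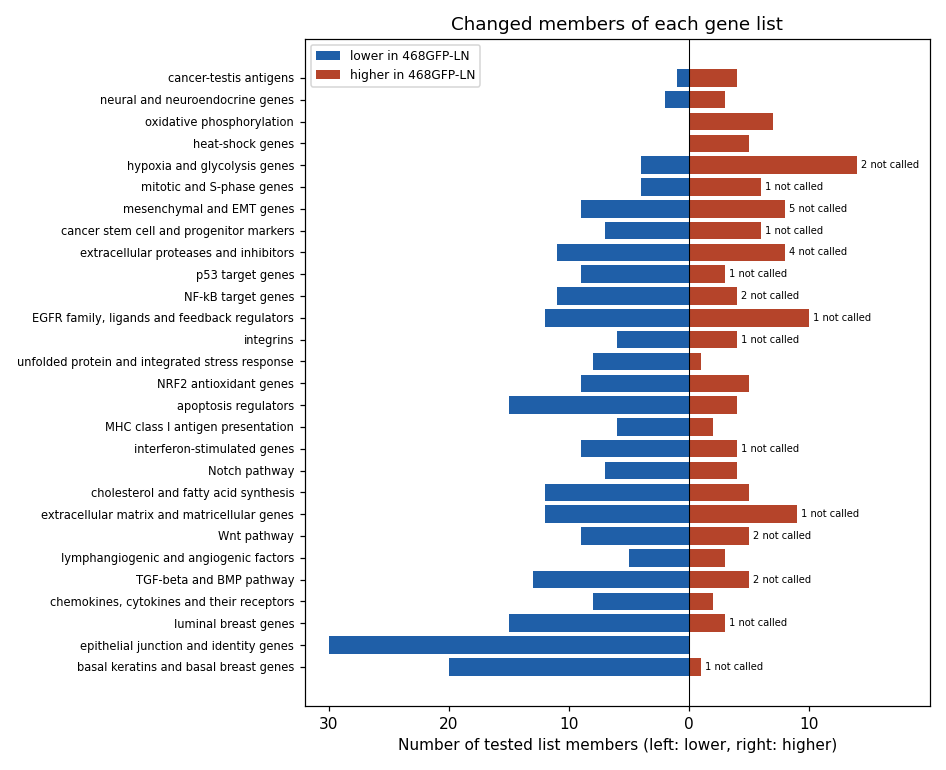
Number of tested members of each testable gene list that were lower (bars to the left) or higher (bars to the right) in the LN line at adjusted p under 0.05, ordered by median log2 change; members that did not pass are given as numbers. Epithelial junction genes fell in 30 of 30 tested cases, from 36 members. Oxidative phosphorylation genes rose in 7 of 7 tested cases, from 51 members.

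Relative to the other tested named genes, 3 of 28 testable lists were called with the preset correlation, and 0 with an estimated correlation. The rotation test fry asks whether a list's genes move one way, without comparing them with other genes. It passed for 26 lists in one direction, and for 28 when any mix of directions counted. As 3962 of the 4088 tested named genes were called, mostly named from a table of changes, a pass in any mix of directions was nearly set beforehand. It is not evidence about the lists. Markers of cells that the cultures should not hold had too few tested members for a list test. Among them LCP1, an actin-bundling protein of leukocytes, rose from 63.9 to 1635, while the leukocyte genes CORO1A and CSF1R fell, from 144 to 5.72 and from 84.6 to 31.6. Of the stromal genes, the proteoglycan LUM rose from 1.04 to 438 and COL1A1 fell from 357 to 6.36. HLA-DPB1, the 1 tested MHC class II gene, rose from 6.51 to 154. IL7R fell from 94.9 to 50.2. MS4A1 had signals of 62.4 and 29.8 (adjusted p = 0.0671), and passed without parental replicate 2 (adjusted p = 0.0342) or LN replicate 2 (adjusted p = 0.0352). It also passed with the mean of all probe sets of a gene. HBB had signals of 64.1 and 99.5 (adjusted p = 0.0171), a call lost without parental replicate 3 (adjusted p = 0.0664), LN replicate 2 (adjusted p = 0.0694) or LN replicate 3 (adjusted p = 0.0574).

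The authors' deposited table held 6554 probe sets, 3055 higher and 3499 lower in the LN line. Its highest fold changes, in the authors' deposited table, were 2491 for CTAG1B, 1189 for CAPN3, 1138 for CTAG2, 1074 for MGC62094 and 1039 for TYR, the key enzyme of melanin synthesis. Those of CTAG1B, CAPN3 and TYR came from other probe sets than the brightest named ones used here. For the latter, the authors' deposited table gives 1496 for CTAG1B, 48.5 for CAPN3 and 78.0 for TYR. Of the table's probe sets, 5982 passed the signal filter here and all 5982 were called, 91.3% of the table. The other 572 lay below the filter. Direction was shared by all 6554. A further 1863 probe sets were called with at least 2-fold changes here but are outside the authors' deposited table. As the table was selected on these arrays, this overlap is not independent evidence.

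Genes from published studies of lymphatic metastasis were compared with all tested probe sets, a test added after the data were seen. Of 410 probe sets on those lists, 187 passed the signal filter. Of these 187, 129 changed, or 69.0%, with 63 higher and 66 lower in the LN line (Fisher's exact adjusted p = 0.0144). Random lists of matched signal changed in 57.2% of members at the median (matched permutation adjusted p = 0.0036). Adjustment covered the pooled lists together with their single-study parts. The single-study parts of the lymphatic metastasis list share probe sets, so their results are not independent of each other or of the pooled result. Both tests treat probe sets as independent, though probe sets of the same gene can change together. They describe these lines only and do not test a link to metastasis. Of the list from Vecchi, 103 of 139 probe sets changed (Fisher's exact adjusted p = 0.00147); for the lists from Feng and Hao the numbers were 40 of 63 (Fisher's exact adjusted p = 0.713) and 42 of 67 (Fisher's exact adjusted p = 0.715). Of the probe sets linked to stem cell-like properties, 246 of 401 changed, or 61.4% (Fisher's exact adjusted p = 0.523; matched median 64.1%).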

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

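All tests in this part were chosen before the data were examined. Probe sets below the signal filter stood outside the comparison of the lines, and a signal appeared there: without the filter, 3521 of these 27306 probe sets were called by limma, 1720 higher in the LN line and 1801 lower.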

How the results depend on the processing

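Tests on the published lists were chosen after the data were seen. The count of changed probe sets was 9595 with the stricter filter, which tested fewer probe sets, and 7356 at adjusted p under 0.05 and at least 2-fold. Other settings gave 13930 (the methods' test per probe set) to 18338 (no filter), and leaving out each array in turn gave 14052 to 16589, the highest without parental replicate 1. The share of the authors' table recovered was 54.3% with the stricter filter, as fewer of its probe sets were tested, 100% with no filter and 91.3% in every other setting, with a leave-one-out range of 91.3% to 91.3%. The number of gene lists called was 5 with the stricter filter, which added luminal breast genes and hypoxia and glycolysis genes, and 0 with an estimated correlation. It was 4 with quantile normalization, and 3 to 4 leaving out each array, with 4 without LN replicate 1. For the lymphatic metastasis genes 77 probe sets changed with the stricter filter, where fewer were tested, and 123 to 131 leaving out each array; for stem cell-like genes the range was 232 to 255. Of 2423 comparisons over 153 named genes, 2417 kept their side of the threshold, 3 fell short of it (HBB), 3 passed it newly (MS4A1) and 0 reversed. Most of these genes were picked for large changes, so this stability was largely set beforehand and does not describe the other calls. With the replicate number as a block, 15816 probe sets were called, 15341 of them shared with the fit without it, and 4 lists, adding hypoxia and glycolysis genes. Deviations of arrays with the same number correlated at 0.0267, 0.0718 and -0.0117, against -0.0567 to 0.0260 for different numbers; these weak correlations were not taken as pairing. Of the 10 splits of the arrays into 3 and 3, only 1, the real one, gave 15981 probe sets, and the highest other gave 0; so few splits cannot give a share under 0.05. Low signals, near background, limit the sizes of the largest folds.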

Other observations

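The melanocyte marker test on markers not examined before and the neighbouring gene test were set out before their results were seen; the tests of epithelial signal, of RB1 and SMAD4 and of actin ratios were chosen after.

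Of 20 heat-shock genes on the list, 5 were tested. They rose in 5 of 5 cases, also adjusted over the list alone, without a call (camera adjusted p = 0.107), with HSPA1B rising from 590 to 2123. Cancer-testis antigens rose in 4 cases and fell in 1, also adjusted over the list alone (camera adjusted p = 0.107). PRAME rose from 20.4 to 650 and MAGEA1 from 316 to 1724, while MAGEA3 fell from 2761 to 1273. Neural genes rose in 3 and fell in 2 of 5 cases (camera adjusted p = 0.516), with SLC6A8, the creatine transporter, rising from 27.9 to 1911. Of 38 stress response genes on the list, 9 were tested. They fell in 8 and rose in 1 of 9 cases (camera adjusted p = 0.107), with PSPH, of serine synthesis, falling from 4390 to 148. Apoptosis regulators fell in 15 and rose in 4 of 19 cases (camera adjusted p = 0.166): BOK fell from 420 to 3.24 and the death receptor FAS rose from 17.7 to 335. For these 3 groups the counts adjusted over the list alone were the same.

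Signalling lists were mixed, with no list called and the same counts adjusted over the list alone. TGF-beta and BMP genes fell in 13 and rose in 5 of 20 cases (camera adjusted p = 0.439), with TGFB2 falling from 1217 to 98.1. Wnt genes fell in 9 and rose in 5 of 16 cases (camera adjusted p = 0.696): WNT6 fell from 1285 to 4.99 and LEF1 rose from 5.44 to 657. Notch genes fell in 7 and rose in 4 of 11 cases (camera adjusted p = 0.696): NOTCH3 fell from 1342 to 10.3 and HEY1 rose from 66.2 to 865. NF-kB targets fell in 11 and rose in 4 of 17 cases (camera adjusted p = 0.471), with LCN2 falling from 638 to 25.6. Interferon-stimulated genes fell in 9 and rose in 4 of 14 cases (camera adjusted p = 0.559), with GBP1 falling from 635 to 40.6. Cytokines and receptors fell in 8 and rose in 2 of 10 cases (camera adjusted p = 0.320): LIF fell from 664 to 7.02 and IL6R rose from 2.45 to 530. Targets of p53 fell in 9 and rose in 3 of 13 cases (camera adjusted p = 0.455), and NRF2 genes fell in 9 and rose in 5 of 14 cases (camera adjusted p = 0.696).

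Melanocytic genes rose and epithelial genes fell together in the LN line. Of 39 melanocyte markers 28 were tested and 28 rose, among them TYR (60.7 to 4640), DCT (90.7 to 4303), MITF (252 to 3590) and SOX10 (35.8 to 2246); 0 of these are in another list, and their names mostly come from the authors' table. The median epithelial signal was 2.81% of that in the parental line. As these genes were named from a table of changes of at least 2-fold, a median well short of the parental signal was set beforehand. Single genes still bear on a minority of other cells among parental cells, which would leave most of each gene's parental signal. For the 16 of 30 genes under 5%, such a minority is argued against. Cells of another line with melanocytic expression in place of a derivative of the parental line are a candidate explanation. Of 30 markers not examined before, 19 were tested and 100% of these rose, against 43.0% of 4060 other named genes (one-sided Fisher's exact p = 1.17e-07). However, a marker low in the parental line passed the signal filter only where it was high in the LN line. Fisher's test also treats markers of 1 cell type as independent, so its p-value does not measure support for this explanation. A change of state in descendants of the parental cells would raise these markers too, so that test does not separate it from another line, and it stays open; against it, RB1 rose from 1.49 to 542 and SMAD4 from 9.36 to 366, a log2 change of 3.93 or more (its other probe sets, below the filter, had signals of 1.86 and 32.0, and of 12.98 and 33.1), and MDA-MB-468 is known to have lost both genes, but DNA was not measured in these files and line identity was not tested.

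Changed named genes next to each other in chromosome order shared their direction more often than chance ordering gives. Unnamed or unchanged genes could lie between the members of a pair. Families were told apart only by the opening letters of the gene symbols, so related genes with unlike symbols were kept. Among 3248 changed named genes, 64.7% of 3076 such pairs shared their direction. The median was 54.6% and the highest value 57.9% in 10000 shuffles within chromosomes (one-sided permutation p = 1e-04, the smallest these can give). DNA copy number differences between the lines may contribute to this; jointly regulated gene clusters were not tested and stay open.

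The array of parental replicate 1 stood apart from the others of its line. Its actin 3' to 5' ratio was 1.75 times the highest of the other arrays, and its GAPDH ratio of 1.26 was also the highest, which may reflect shorter or degraded RNA. Without it, 16589 probe sets were called, 15355 of them also called with it.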
